A study of Homo sapiens with 35 samples.

How the data were processed

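The labels describe 35 samples of 22Rv1, a human prostate cancer cell line, either unedited or with a poly-A signal knocked into the HOTAIR gene by CRISPR/Cas9. HOTAIR is a long non-coding RNA transcribed from the HOXC cluster, and an inserted poly-A signal is meant to end its transcription early. The assays were RNA-seq (5 samples), ChIP-seq (18), CUT&Tag (6) and ChIRP-seq (6). Only ChIRP-seq was analysed here, as 2 deposited peak lists that stand for 4 of the samples: 1 list for a second run of unedited cells and 1 list for knock-in cells. ChIRP-seq pulls down fixed chromatin with DNA probes against an RNA and sequences the DNA that comes with it. Each list merges 2 probe pools, called odd and even in the labels, which are meant to share no probe. The other samples, among them a first ChIRP run of unedited cells and the RNA-seq, ChIP-seq and CUT&Tag samples, were not analysed here. The series describes 2 knock-in lines, and the labels do not give the line behind the knock-in ChIRP list.

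Per the labels' protocols, cells were fixed with glutaraldehyde, and nuclei were sheared by sonication before hybridization with the probes. The submitters' processing notes name STAR, MACS2 and the genome build hg38 for the ChIRP samples, with no version. MACS2 is a peak caller, and per the file headers each deposited list gives its columns: position, length, summit, pileup, -log10 p, fold enrichment and -log10 q. The deposited pileup is a coverage signal, the height of stacked fragments at the summit. The deposited fold enrichment was read as a ratio of pileup to the local background after the same constant is added to both, as in the relation below. The deposited p and q are given as -log10 values. The deposited columns for correlation, fold differences and average coverage are scores that the headers do not define. By their names and the merged pools they were read as a comparison of the odd with the even pool, which is a reading and not a stated fact. These scores were exactly 0 for the correlation of 63.6% of unedited peaks. Average coverage had a median of 2.37 in the unedited list and 2695 in the knock-in list, so that it was taken to be on different scales and was used for nothing. Scaling of the reads, the control library, the caller's settings and any filter behind the lists are not given in the sources used here. Fold enrichments and p-values were used to describe, rank and filter peaks within a list. Comparisons between lists draw on them only for the background recovered from them and where parts of the lists cut by fold enrichment are set side by side.

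The depth behind each list is not stated. The local background was therefore recovered from each peak as (pileup + 1) / fold enrichment - 1. With a Poisson model this background and the pileup gave back the deposited -log10 p to within 0.00175% in the unedited list and 0.135% in the knock-in list. The lowest background, which is the caller's floor for a library, was 0.0370 in the unedited list and 0.000115 in the knock-in list. The upper quartile of the background was 0.0884 in the unedited list and 0.000164 in the knock-in list. Fold enrichment was therefore close to pileup + 1 for most peaks. Ranks and cuts by fold enrichment thus largely follow the pileup, and are not a large ratio over background. Peaks in the knock-in list were never narrower than 192 bp and in the unedited list never narrower than 70 bp. Peak names were numbered from 1 without a gap in both lists.

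Peaks of the unedited list lay on chromosomes 10, 11, 12, 13, 15, 16, 17, X and Y and on scaffolds, and those of the knock-in list on X, Y and 1 scaffold. Peaks on other chromosomes were not analysed here, and the lists were compared on X. Both lists were made from merged pools with 1 list per genotype, so there is no replicate. Counts are given without a p-value between genotypes, and placement tests describe the lists, not the genotypes.

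Gene positions came from a table of RefSeq gene spans on GRCh38.p14, the same assembly as hg38, with 6948 protein-coding genes on the 9 chromosomes. The table holds no strand, exon or genome sequence. The promoter, exon and intron classes planned before the data were examined were therefore replaced by gene ends (midpoint within 1 kb of either end of a protein-coding span), gene bodies and the rest. The planned 5 kb upstream of a gene became 5 kb to either side of its span. Random placement, planned to avoid assembly gaps, was made within bins of 1 Mb that held a peak of either list. GC content of peaks and their similarity to the HOTAIR sequence were planned and were not analysed here.

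Overlap of the lists was counted at 1 bp or more and compared with 1000 placements of the knock-in peaks on their own chromosomes, with widths kept, which is a permutation of positions. Its p is the share of placements with at least as many overlaps (1-sided). Gene classes were compared with 1000 placements of the knock-in list and 100 of the unedited list (2-sided). Peaks at HOTAIR were compared with 10000 random windows of the same length on chromosome 12. Of 12 gene lists with 185 genes, fixed before the data were examined, each with members on the 9 chromosomes was compared with 10000 random lists of protein-coding genes. The share of genes with a peak was matched on gene length in 20 bins. Peaks per 100 kb of the gene with its flanks were matched on length and chromosome, a step added after seeing the density of chromosome 12. Caller values of overlapping and other peaks were compared by the difference of medians in a permutation test with 100000 resamples. Along a chromosome, rank correlations with gene counts per 1 Mb bin were tested by shifting one profile around the chromosome, with Benjamini-Hochberg adjustment over 10 relations. Bins near HOTAIR were also compared with the 10 bins of chromosome 12 nearest in gene number, and a list of 45 cancer genes had an interval from 10000 bootstrap draws over its genes. A share of peaks has an exact 95% binomial interval, which covers counting error only.

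Genes are named by a rule set before the data were examined. It takes HOTAIR, then up to 6 genes of each list by fold enrichment, and the 10 protein-coding genes with the highest unedited peaks. It further takes the 10 genes of at least 10 kb with the most unedited peaks per kb, the 10 genes with the highest knock-in peaks, and the 10 with the highest knock-in peaks that overlap no unedited peak. Alternatives set before the data were examined included the upper 50% and upper 10% of each list by fold enrichment. Peaks tied at a cut were all kept, so such a part can hold more than its named share. The other alternatives set then were merging of peaks, other overlap rules, local placement by 50 to 500 kb, and other windows at HOTAIR and at gene ends. They also covered all annotated genes, 5 kb around gene ends, and matching on neighbouring genes. Added later were a correlation score above 0.3, a pileup of at least 5, means in place of medians, matching of density on length only, and the alternatives for chromosome 12 and for gene density.

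The placement test was tested on simulated data with 393 peaks on X. It called 1 of 20 sets with no planted overlap, and 20 of 20 sets with 10% of the peaks planted on unedited peaks. For density, run on 6948 genes with lists of 15 genes, it called 0 of 50 lists at a ratio of 1, 43 of 50 at a ratio of 1.5 and 50 of 50 at a ratio of 2. Lists with fewer genes have less power than that. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.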

Results

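ChIRP-seq was used to map where HOTAIR RNA sits on chromatin of 22Rv1 prostate cancer cells, and whether that map is lost once a poly-A signal is inserted into HOTAIR. The list for unedited cells held 232729 peaks, of which 231357 lay on 9 chromosomes and 1372 (0.590%) on scaffolds. The list for knock-in cells held 396 peaks, of which 393 lay on chromosome X, 2 on Y and 1 on a scaffold. Each list was made by the authors from 1 odd and 1 even probe pool, so no count has a replicate error. The depth behind either list is unknown.

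Unedited cells had peaks along each chromosome listed, and knock-in cells had few peaks where both could be compared. On chromosome X the unedited list held 15552 peaks and the knock-in list 393, a ratio of 39.6. Unedited peaks were narrow, with a median width of 167 bp (range 70 to 4693), and covered 39.7 Mb. Knock-in peaks had a median width of 388 bp (range 192 to 864) and covered 0.144 Mb. Exactly at the smallest width of their list were 12.1% of unedited and 11.6% of knock-in peaks. That width differs between the lists and the caller's settings are not given, so widths and covered lengths may not be comparable. The median pileup was 3 in both lists, and a pileup of 1 or 2 made up 23.3% of unedited and 33.8% of knock-in peaks. The local background recovered from the caller's values was lower in the knock-in list, with a median of 0.000118 against 0.0471. Fewer reads or a different scaling of the coverage would both give such values, so equal depth behind the 2 counts cannot be assumed. The deposited correlation, read as one between the probe pools, was above 0.3 for 33243 unedited peaks (14.3%) and 169 knock-in peaks (42.7%). It was below 0 for 16.9% and 36.1% and exactly 0 for 63.6% and 9.60%, so these shares do not rank the lists by concordance. With that filter the ratio on X was 14.1.

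Chromosome 12, which carries HOTAIR, was the most densely covered chromosome of the unedited list. It held 59521 peaks, 25.7% of those on the 9 chromosomes, with a median of 434 per 1 Mb bin. The median over bins of the other 6 autosomes was 254, and their own medians ran from 231 on chromosome 16 to 286 on chromosome 13. The ratio of chromosome 12 to these was 1.71, and 130 of its 134 bins lay above the median of the others. Chromosome X had a median of 100 peaks per bin, 0.394 times that of the 6 autosomes.

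**Figure D1:**
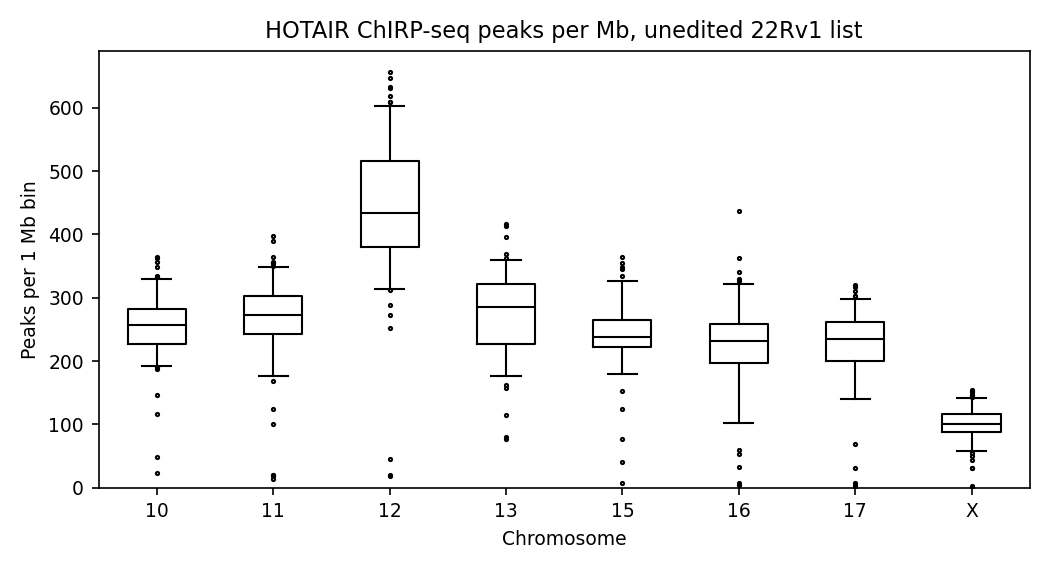
Peaks of the unedited list per 1 Mb bin (vertical axis, count) on 8 of its 9 chromosomes (horizontal axis). Boxes span the quartiles with the median as a line, whiskers reach the 5th and 95th percentiles, and points are bins beyond them; the median of chromosome 12 is 434 and that of X is 100.

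The HOTAIR gene itself, the source of the RNA that the probes target, was not a site of unusually many peaks. The gene lies at 53962312 to 53974954 on chromosome 12 (hg38), between HOXC12 and HOXC10 and partly within the span of HOXC11, and held 7 unedited peaks. Random windows of its length on chromosome 12 held 5.67 on average, and 37.2% of them held as many. With 100 kb to each side, which takes in HOXC13 to HOXC4, there were 79 peaks against 94.4 in random windows. The highest peak in the gene lay at 53965701 to 53965944, with a pileup of 6 and a fold enrichment of 6.51. Its deposited correlation, read as one between the pools, was 0.966. On chromosome 12, 2606 peaks had a fold enrichment at least as high. The knock-in list held 0 peaks on chromosome 12 and on the other autosomes of the unedited list. The unedited list itself lacks the remaining autosomes, so the absence of a whole chromosome from a list need not reflect the genotype. How the lists came to lack chromosomes is not known. A lack of knock-in peaks at HOTAIR could therefore not be separated from the absence of every autosome from that list.

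**Figure D2:**
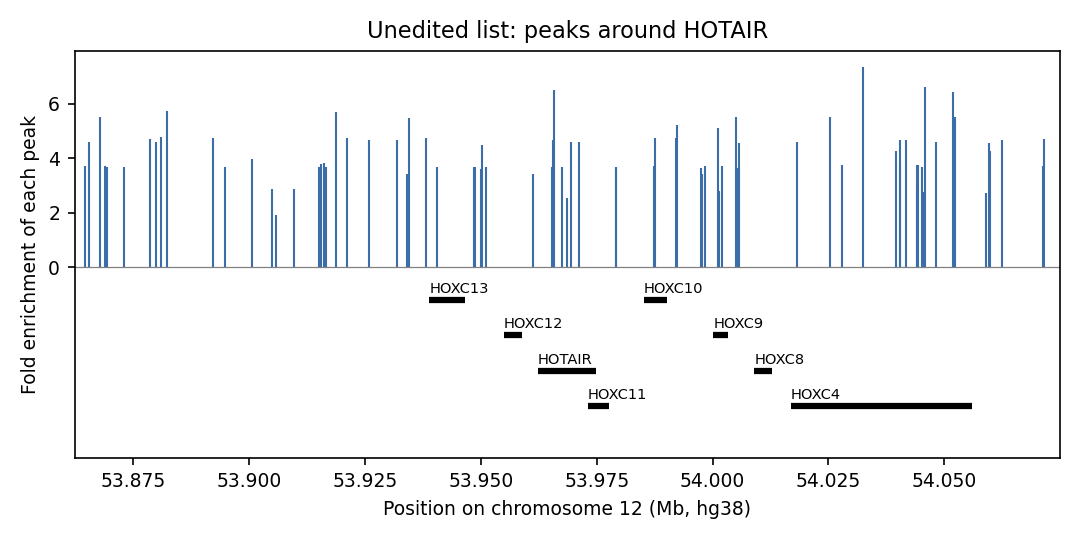
Unedited peaks around HOTAIR, with position on chromosome 12 in Mb (hg38) on the horizontal axis and the authors' fold enrichment of each peak on the vertical axis. Vertical lines are peaks at their midpoints and black bars are gene spans; the 7 peaks within HOTAIR, the highest at 6.51, stand among the 79 peaks of the window.

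Few knock-in peaks overlapped unedited peaks, and random placement also gave few overlaps. Of 396 knock-in peaks, 27 (6.82%, exact 95% interval 4.54 to 9.77) overlapped an unedited peak by 1 bp or more. Random placement of the same peaks gave 20.4 overlaps on average (standard deviation 4.41), and 84 of 1000 placements gave at least 27, so the overlap did not exceed placement by this test (permutation p = 0.0849). On X alone 25 of 393 peaks overlapped, against 20.2 by placement (permutation p = 0.169). The smallest overlap planted in simulation was 10% of the peaks, so the power for a smaller excess is unknown. Overlapping peaks included the highest of the knock-in list, in HAUS7, which encodes a subunit of the augmin complex of the mitotic spindle. Fold enrichment takes few distinct values at such low pileups, so the difference of medians, which was 0 in both lists (permutation p = 1), cannot show a small difference. Means, compared after the data were seen, were 4.48 for the 27 overlapping and 4.23 for the 369 other knock-in peaks (permutation p = 0.437). In the unedited list on X they were 4.30 for 26 overlapping and 3.91 for 15526 other peaks (permutation p = 0.107).

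The lists differed in where their peaks lay on X. Some stretches held a larger share of the knock-in than of the unedited peaks, although most knock-in peaks lay outside those named here. The first 3 Mb, most of which is the pseudoautosomal region that X shares with Y, held 44 (11.2%) of the knock-in and 404 (2.60%) of the unedited peaks on X. From 152 Mb to the end of the long arm there were 35 (8.91%) against 540 (3.47%), and 22 of the 35 lay in the 1 Mb bin at 153 Mb, which holds 30 protein-coding genes. The bin at 49 Mb, inside the short arm, held 8 (2.04%) against 108 (0.694%). Other bins away from the ends of X held more knock-in peaks, such as 10 against 85 at 40 Mb and 10 against 97 at 119 Mb. Sequence in the pseudoautosomal region is the same on X and Y, so peaks there cannot be assigned to one of them. Across 155 bins of 1 Mb, knock-in peaks followed the number of protein-coding genes (Spearman rho 0.529, Pearson r 0.507), with the smallest p that shifting along X can give (0.00645, adjusted 0.0249). Without the 2 bins with most genes, rho was 0.511 and r was 0.402. For unedited peaks on X, rho was 0.101 and r was 0.134 (p = 0.277, adjusted 0.347). Bins of a chromosome are not independent replicates, and the difference between the 2 correlations was not tested.

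**Figure D3:**
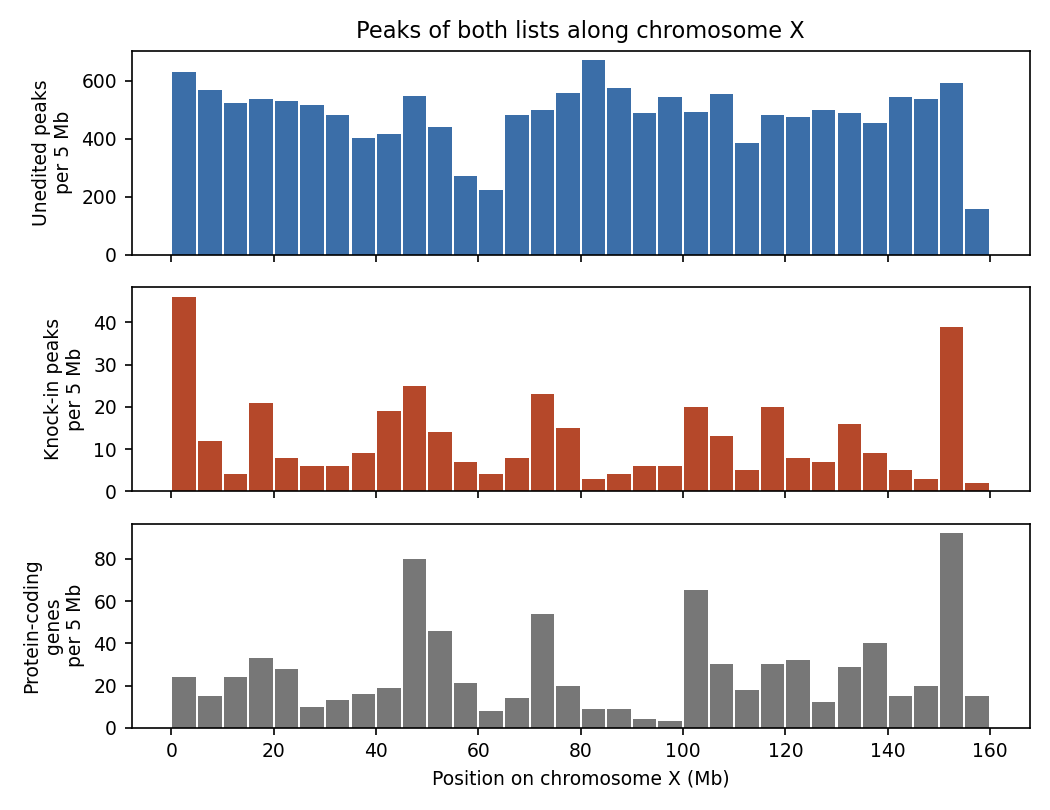
Peaks of the unedited list (top), peaks of the knock-in list (middle) and protein-coding genes (bottom), each as a count per 5 Mb along chromosome X (horizontal axis, Mb). The 2 peak panels have different vertical scales, since X holds 15552 unedited and 393 knock-in peaks; knock-in peaks are most frequent in the first 5 Mb and in the gene-dense stretch around 153 Mb.

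Knock-in peaks were found at gene ends more often than by placement, and unedited peaks less often. Of 395 knock-in peaks on X and Y, 6.08% had their midpoint within 1 kb of an end of a protein-coding gene, against 2.05% by placement. None of 1000 placements reached this share (permutation p = 0.00200, the smallest that they can give). Such placement does not keep the local gene density, which knock-in peaks followed on X. Placement near each peak was not run for gene ends, so an excess beyond that of gene-dense stretches was not tested. The upper 10% of the knock-in list by fold enrichment held 62 of its 396 peaks, since ties at the cut were kept. There the share was 3.23% against 2.09% (permutation p = 0.747). Over all 9 chromosomes 1.90% of unedited peaks lay at gene ends, against 2.76% by placement, and 46.2% lay in gene bodies, against 43.5% (permutation p = 0.0198 for both, the smallest that 100 placements can give). On X alone, 299 of 15552 unedited peaks (1.92%, exact 95% interval 1.71 to 2.15) were at gene ends, against 24 of 393 knock-in peaks (6.11%, interval 3.95 to 8.95), which is 3.18 times the share. Unedited peaks at gene ends on X did not differ from placement, at 1.92% against 2.06% (permutation p = 0.198).

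With peaks this dense, 6532 of 6948 protein-coding genes (94.0%) had an unedited peak within their span or 5 kb of it, so that having a peak tells little about a gene. For all 11 gene lists with members on these chromosomes, the share of genes with a peak was within the central 95% of random lists, and so was the density of peaks once matched on length and chromosome. Percentiles of gene lists, here and below, were not adjusted for the number of lists and settings, so some can pass that limit by chance. HOXD genes, which HOTAIR is known for repressing in fibroblasts, lie on a chromosome that neither list covers and were not analysed here.

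In the whole unedited list, genes of androgen response had peaks as random genes do. All 7 members on the listed chromosomes had peaks, with 27.5 per 100 kb against 27.8 in random lists. AR, the androgen receptor gene itself, at 67544021 to 67730619 on X, had 51 peaks, or 25.9 per 100 kb, higher than 91.5% of genes on X, where the median is 9.79. ABCC4, a transporter gene, held the highest peak of the list at a fold enrichment of 8.33, followed by CAMKK2, the gene of a kinase, at 8.27 and MAF, a transcription factor gene, at 7.71. None of the 7 had a knock-in peak, and only AR lies on X.

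Genes of the cell cycle averaged 29.7 peaks per 100 kb against 25.1 in random lists, at the 87.3rd percentile. Relative to random lists this was 1.19, and it was 1.69 with a correlation above 0.3 (97.2nd percentile) and 1.95 in the upper 10% of peaks (96.0th percentile), within the central 95% each time. TOP2A, the gene of DNA topoisomerase II alpha, had 21 peaks or 53.3 per 100 kb, more than 98.4% of genes on chromosome 17, and its highest peak, with a fold enrichment of 9.26, lay just beyond the end of its span at 40417926 to 40418273. CDC6, a replication licensing gene, had 7 peaks with a highest value of 6.75.

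Genes of the transcription machinery averaged 24.8 peaks per 100 kb against 24.7 in random lists. Counting only peaks with a correlation above 0.3, an added setting, their density was 1.97 times that of random lists (98.5th percentile), and in the upper 10% of peaks by fold enrichment 1.23 times (72.2nd percentile). MED12, a subunit of the Mediator kinase module, stood out on X with 19 peaks or 56.1 per 100 kb, above 99.5% of genes on that chromosome. MED12 also had 1 knock-in peak, with a fold enrichment of 5.999. CREBBP, an acetyltransferase gene, had 43 peaks with a highest value of 8.27. HEXIM1, which encodes an inhibitor of elongation factor P-TEFb, had 0 peaks and is named after its value was seen. Of the list of PRC2 and LSD1 complex subunits, which are reported partners of HOTAIR, only PRC2 genes lay on the listed chromosomes, and their density was 29.4 per 100 kb against 26.6, a direction that turned with a correlation above 0.3 (0.671 times random lists) and in the upper 10% of peaks by fold enrichment (0.613 times). All 5 had peaks (EZH1, SUZ12, EED, RBBP7 and AEBP2), with highest fold enrichments from 4.79 for RBBP7 to 7.64 for AEBP2, and RBBP7 had 1 knock-in peak.

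The HOXC cluster around HOTAIR, with 9 genes counted, averaged 34.3 peaks per 100 kb against 33.3 in random lists of chromosome 12. These genes are neighbours, and HOXC4, HOXC5 and HOXC6 overlap and share their highest peak. Random lists draw genes independently, so their central 95% may be too narrow for this cluster. With a correlation above 0.3 the density was 0.763 times that of random lists, and in the upper 10% of peaks 0.549 times. HOXC9 had 9 peaks, at 68.3 per 100 kb, and HOXC6 had 4, at 16.7. Among genes reported as repressed by HOTAIR in other cells, 4 of 5 had a peak against 97.9% in random lists (5.14th percentile). Within 5 kb of either gene end only, the share was 0.649 times that of random lists (2.45th percentile). Percentiles count tied random lists only in part, and a share of 5 genes takes few values. More random lists were as low or lower than these percentiles give, so this share is not shown to lie past the central 95%. CDH1, the E-cadherin gene, had 33 peaks with a highest value of 10.1, PTEN had 30, PGR had 39 and WIF1 had 33, while PCDH20, a protocadherin gene, had 0. Genes of invasion and epithelial to mesenchymal transition had 29.0 per 100 kb against 24.2, and ZEB1, a repressor of E-cadherin, held the highest peak of all listed genes, at a fold enrichment of 11.6.

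Peaks were also found at markers of other lineages, at densities near the upper limit of random lists. Neuroendocrine markers had 41.2 peaks per 100 kb against 30.01 (96.7th percentile), led by SYT1, a synaptic vesicle gene, with 404 peaks or 67.6 per 100 kb over its 588 kb. Their density was 1.32 times that of random lists with a correlation above 0.3 (78.27th percentile). In the upper 10% it was 1.37 times (78.45th percentile). Genes of blood, liver and other tissues had 32.4 against 23.0 (95.6th percentile), with CD19, a B cell gene, at 57.6, and 2.26 times the density of random lists (98.9th percentile) in peaks with a correlation above 0.3 but 1.22 times (67.2nd percentile) in the upper 10%. Luminal prostate genes had 33.6 against 29.8, with 7 peaks at KRT18, a luminal keratin gene, and 4 at HOXB13, a prostate homeobox gene. That direction turned with a correlation above 0.3 (0.825 times random lists) and in the upper 10% (0.801 times). Reference genes had 24.4 against 25.4, but 2.06 times the density of random lists (98.0th percentile) in peaks with a correlation above 0.3. Of these, 6 of 8 had a peak of the upper 10% by fold enrichment, against 30.1% in random lists (99.6th percentile), among them PGK1 at 8.68 and RPLP0 at 7.67.

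The highest unedited peaks lay in or near single genes across the listed chromosomes. The first was in GAGE12B (49345927 to 49346223 on X), with a fold enrichment of 20.02, and 1 peak inside GAGE12J, within 5 kb of GAGE10, reached 16.99. GAGE genes are a cancer-testis family of near-identical copies, so reads there may belong to another copy and these peaks are uncertain. A peak at 65832076 to 65832622 on chromosome 11, near the start of the SNX32 span and inside LOC124902693, reached 17.2. TLE3, a corepressor gene, reached 16.6, SFXN2, a mitochondrial carrier gene, 15.6, and DUOX2, an oxidase gene, 15.2. The DUOX2 peak had a correlation of -0.54, which would mean that the pools did not share its shape if the score is read rightly. RAD52, a recombination gene, reached 14.2 with a correlation of 0.982. All lay inside the gene span, except where stated, and the gene table does not tell exon from intron.

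Most of the 10 genes with the highest density per kb lay on chromosome 12, where peaks are dense throughout. They were SPIC, KLRF2, MUC19, COL2A1, SLCO1B1, WASHC3 and GTSF1, from 83.1 per 100 kb at SPIC to 72.3 at GTSF1. COL17A1, a hemidesmosome collagen gene on chromosome 10, had 69.7 and TMPRSS5, a protease gene on chromosome 11, had 69.5. NTRK3, a neurotrophin receptor gene on chromosome 15 (87859751 to 88256739), had 284 peaks, or 69.8 per 100 kb against a median of 22.7 on its chromosome. Its peaks were not spread over the gene. A segment of 190 kb from 87940001 to 88130000 held 230 of them and was covered by peaks over 72.1% of its length, against 4.15% of chromosome 15. The 100 kb on its left and right were covered to 2.87% and 5.61%. Peaks in the segment had a median width of 434 bp and a median pileup of 7, against 167 bp and 3 on the chromosome.

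**Figure D4:**
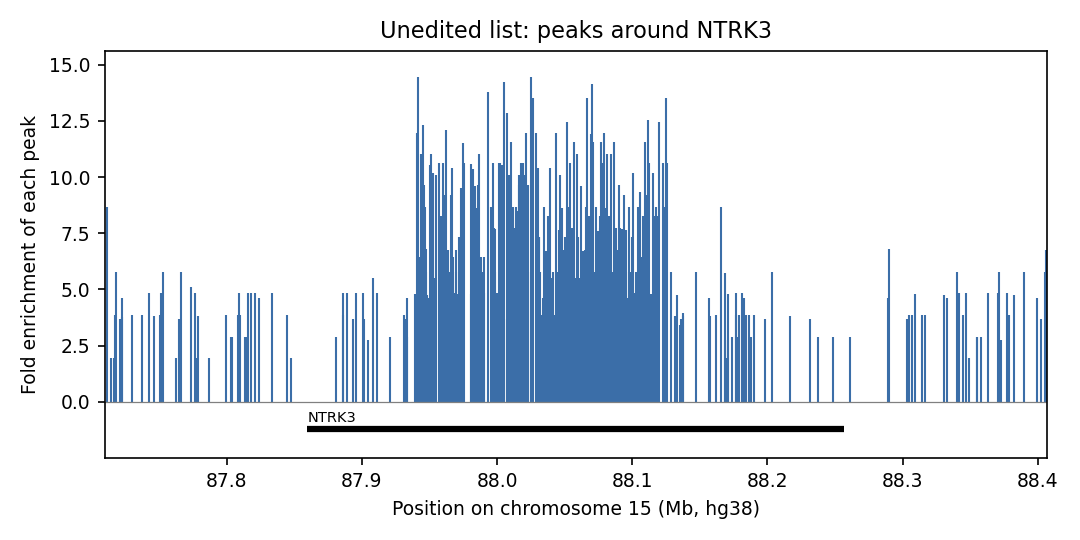
Unedited peaks around NTRK3, with position on chromosome 15 in Mb (hg38) on the horizontal axis and the authors' fold enrichment of each peak on the vertical axis. Vertical lines are peaks at their midpoints and the black bar is the span of NTRK3; dense, high peaks start and stop inside the gene, over a segment of 190 kb.

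In knock-in cells the highest peaks all lay on X. HAUS7 led at a fold enrichment of 9.999 (153463880 to 153464393), and a second peak in HAUS7 reached 7.998. CRLF2, a cytokine receptor gene in the pseudoautosomal region, and DUSP9, a phosphatase gene with its peak within 5 kb of the span, both reached 8.999. SHROOM2, an actin regulator gene, and ATP2B3, a calcium pump gene, reached 7.999. FAM9A, SCML2, ATRX and a peak shared by RAB33A and ELF4 reached 6.999, ATRX being a chromatin remodeler gene and SCML2 a Polycomb gene. Except for the first HAUS7 peak, all of these had no unedited peak at the same place, and part of the naming rule chose them for that. Other knock-in peaks at 6.999 did overlap unedited peaks. They include those at TENT5D and LOC112268307, which are named after their values were seen. The fold differences score, read as one between the probe pools, had a median of 16.1 in the knock-in list and was above 2 in 98.5% of its peaks. In the unedited list the median was 1.36, and 21.4% of peaks were above 2. The headers do not define this score and its scale may differ between the lists, so disagreement of the pools does not follow. Of 848 protein-coding genes on X, 148 had a knock-in peak within 5 kb. HAUS7 with 6, ATP2B3 and BCOR with 5 each, and PPP2R3B and SHROOM2 with 4 each had the most, of which BCOR and PPP2R3B are named after their values were seen.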

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

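Tests with a correlation score above 0.3, a pileup of at least 5, means, and density matched on length only were chosen after the data were seen. Over 34 results and 118 alternatives, 84 kept their direction and their side of the threshold, or their size, and 18 turned their direction, most of them gene lists close to random ones. The overlap of the lists stayed between 1.07 and 1.64 times placement and passed the threshold in none of its 8 alternatives, and the ratio of chromosome 12 to the other autosomes stayed between 1.57 and 1.69. Low pileup limits both lists, since 33.8% of knock-in and 23.3% of unedited peaks have a pileup of 1 or 2.

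Counts fell by construction under stricter values. The unedited list held 127179 peaks in its upper 50% by fold enrichment, 23324 in its upper 10% and 33243 with a correlation above 0.3. The knock-in list held 227, 62 and 169. Ties at a cut were kept, so the parts by fold enrichment can exceed their named share, as with 62 of 396 knock-in peaks. The ratio on X, 39.6 as deposited, was 42.3 in the upper 50% and 24.8 in the upper 10% of both lists. Equal parts of each list largely fix such a ratio in advance, and ties shift it, so these values do not measure stringency. With a correlation above 0.3 the ratio was 14.1, and with a pileup of at least 5 it was 21.2. It therefore depends on such cuts, while the unedited list stays the longer one. At HOTAIR the ratio to random windows was 0.837 with 100 kb to each side and 1.24 for the gene body only. The excess of knock-in peaks at gene ends was 1.55 times placement in the upper 10% (permutation p = 0.747), where 62 peaks remain. Density relative to random lists matched on length only was 1.57 for HOXC genes and 1.73 for neuroendocrine markers, both past the central 95%. These lists lie largely on chromosome 12, which that matching leaves in. For HOXC genes, which neighbour and partly overlap one another, that limit may also be too narrow. With a correlation above 0.3, density was 2.06 for reference genes, 2.26 for other lineages and 1.97 for the transcription machinery, all past the central 95%, and reference genes reached 2.49 in the upper 10% against 0.963 in the whole list. Genes reported as repressed by HOTAIR had a peak within 5 kb of a gene end at 0.649 times the share of random lists (2.45th percentile). Tied random lists count there only in part, so this share is not shown to lie past the central 95%. The cause of the last 5 changes was not tested.

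Other gene lists crossed the level of random lists while staying in their central 95%. Relative density with a correlation above 0.3 and in the upper 10% was 0.763 and 0.549 for HOXC genes, 0.671 and 0.613 for PRC2 subunits, 0.825 and 0.801 for luminal genes, and 1.22 and 1.42 for androgen response genes. Matched on length only, it was 1.03 for androgen response, 1.04 for genes reported as repressed by HOTAIR, 1.12 for reference genes and 0.991 for the transcription machinery. The share of genes with a peak of the upper 10%, relative to random lists, was 0.980 for androgen response, 1.084 for genes reported as repressed and 1.24 for the transcription machinery. The cause of these changes was not tested.

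No paired analysis was possible because each genotype is 1 merged list, and no test compared replicates. Other settings for GC content and for HOTAIR sequence similarity, chosen before the data were examined, were not run, since the genome sequence was not used here.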

Other observations

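Tests chosen only after their result was seen were that of spread from HOTAIR, the 3 on the low count of knock-in peaks, the share of concordant peaks in gene bodies, the match on gene number near HOTAIR, and the values of all peaks at short genes and of concordant peaks and the bootstrap interval at cancer genes. Unedited peaks with a deposited correlation above 0.3, read as concordance of the probe pools, lay in gene bodies more often than the whole list. Their share was 50.5% against 43.6% by placement (1.16 times), where the whole list had 1.06 times. One hypothesis was that coding sequence is captured whatever its expression. Olfactory receptor and keratin-associated protein genes with spans under 3 kb, 164 in all, are nearly all coding and largely silent outside their tissues. They held 2 concordant peaks inside and 60 in their 5 kb flanks, 0.325 times the density (exact 95% interval 0.0384 to 1.22), and 7 against 392 of all peaks, 0.174 times (0.0694 to 0.362). Since peaks of any kind are rare inside these genes, for a reason not tested here, the low density of concordant peaks does not decide on the hypothesis, and capture of coding sequence cannot be told apart from other reasons for the excess in gene bodies.

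On X, knock-in peaks rose with gene density and unedited peaks on 2 autosomes fell with it. Rho of unedited peaks was -0.57 on chromosome 12 and -0.31 on chromosome 10 (adjusted p = 0.0249 for both), and on chromosome 11 it was -0.35 (adjusted p = 0.0919). On chromosomes 13, 15 and 16 it was -0.43, -0.23 and -0.09, and on chromosome 17 it was 0.19 (adjusted p from 0.139 to 0.648), so the relation does not hold on every autosome. The hypothesis that the 2 genotypes have opposite relations to gene density on X needed a rho of at most 0 for unedited peaks. The knock-in list gave 0.529, the unedited list gave 0.101 with p = 0.277, and the lists had a rho of 0.02 with each other. Opposite and merely unequal relations cannot be told apart on X, because the unedited value does not differ from 0 by this test.

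The knock-in list is short on the chromosome that both lists cover. The absence of autosomes cannot be the whole of it, since on X alone the unedited list was 39.6 times as long. A lower background coverage is a candidate explanation that the caller's values go with: the lowest background was 321.9 times higher in the unedited list, although a different scaling of the coverage would give the same values and stays open. Loss of HOTAIR RNA, the biological explanation that the design names, cannot be told apart from it, because the median backgrounds differ by a factor of 400.4 and the peaks over HOTAIR lie on an autosome that the knock-in list lacks. Libraries of like depth for both genotypes would be needed to separate them.

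Chromosome 12 has 1.71 times the peak density of the other 6 autosomes. Spread of HOTAIR in cis along its own chromosome would place peaks near the gene, but bins within 5 Mb of HOTAIR had 390 peaks per Mb against 449 on the rest of the chromosome, a ratio of 0.869. The bins near HOTAIR are rich in genes (median 28 against 5), and against the 10 other bins nearest in gene number for each the ratio was 1.03 (SD over bins 0.0532), so that a weak spread in cis cannot be told apart from none. More copies of chromosome 12 in these cells may account for the pattern, since density between genes was also higher, 455 against 238 per Mb or 1.91 times, as it was within genes, at 1.70 times. Copy number itself was not analysed here, and binding of HOTAIR over the whole of chromosome 12 stays open as untested.

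In NTRK3, the dense segment begins and ends inside the gene. Binding over the whole transcribed gene is argued against, because 19 of its 41 windows of 10 kb were dense (46.3%), in 1 run. More DNA copies of the segment may account for it. Inside the gene all 19 windows from the first to the last dense one were dense (100%), as a gained or added piece of DNA would give. The segment was bounded by its own dense windows, and any unbroken signal would give the same, so this value does not decide on the cause. A further dense window, starting at 88600001, lay beyond the gene. DNA of this segment from outside the cells would look the same and stays open. A further hypothesis was that DNA captured with a panel of cancer genes had mixed in. For it, 45 other cancer genes, listed before the test, were compared with matched lists. Their density in the upper 10% of peaks by fold enrichment was 1.07 times that of these lists (bootstrap 95% interval over genes 0.831 to 1.32). This was under the 1.5 that was predicted, so as a set they did not share the density of NTRK3. A mean over whole spans of these genes could not show capture of parts of them or of only a few. The hypothesis therefore stays open. A smaller excess in these genes, 1.13 times for all peaks (98.7th percentile) and 1.47 times for concordant peaks (99.97th percentile), is left unexplained; at the latter setting other gene lists ran from 0.671 for PRC2 subunits to 2.26 for genes of other lineages.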
